A study of Arabidopsis thaliana with 8 samples.

How the data were processed

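RNA of 8 Arabidopsis thaliana samples (total RNA, ecotype Landsberg) was measured on expression arrays, 1 value per probe and sample. Per the labels, 4 samples were wild type (WT) and 4 were from the petc mutant, which lacks the Rieske protein of the cytochrome b6f complex of photosynthetic electron transport. Each group carried the replicate numbers 1 to 4. The labels do not say whether the replicates came from separate plants, RNA extracts or hybridisations, so the p-values measure the spread between these samples, which may be technical. Tissue, age and growth conditions are not given in the sources used here.

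The deposited values are intensities on a linear scale, one column per sample, with 3439 probes and no negative value. The scanner, the background correction, the scaling and any filter the authors applied are not given in the sources used here. Between 430 and 461 probes per sample were listed at exactly 0, and 309 of them were at 0 in all 8 samples. Between 2 and 4 probes per sample lay at a ceiling of 100. The mean deposited intensity was 0.956 to 1.00 per sample, and the total was 3287 to 3440. The unit is not given and is treated as arbitrary, and whether each array was scaled to a common mean is not known. The number of arrays limits the precision. All 8 columns were used, and no other per-sample column was set aside.

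Probes were named through the platform annotation held by GEO. It pairs 692 probes with 1 gene, 870 with several genes and 1877 with none, and no gene was named from a probe with several. Of the 692, 690 were found in the RefSeq gene table of the assembly TAIR10.1, which was used for names only. The files name no genome build, so no coordinates are given. Probe sequences were not used here, so the annotation could not be checked against them. PETC, the gene mutated in petc, is not analysed here.

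Values of 0 were treated as missing and the others were taken to log2. Because the column medians differed by up to 0.131 on the log2 scale, more than the limit of 0.1 set before the data were examined, the arrays were quantile normalised. Probes with at least 3 values in each group were tested, which left 2947 probes, 595 of them with 1 gene. Expression in petc and WT was compared with limma 3.58.1 (lmFit and eBayes) in R 4.3.3, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Intensities are given as the mean of the deposited values with their SD, while fold changes and their SE come from the normalised log2 values, so the ratio of the printed intensities can differ from the fold change. Figures were drawn with matplotlib.

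Gene lists were fixed before the data were examined: 20 lists with 381 genes, of which 15 genes in 8 lists were measured on a single-gene probe. The lists with no measured member were electron transport and ATP synthase, carotenoid and isoprenoid synthesis, plastid chaperones and proteases, plastid protein import, starch and sugar metabolism and transport, photorespiration, aromatic amino acid synthesis, nitrogen and sulfur assimilation, plastid transcription, non-green plastid and root isoforms, senescence, and cytosolic reference genes. No control of cell type or leaf age could therefore be made from them. Lists with at least 3 measured members were tested with camera, with a preset correlation between genes of 0.01 and with an estimated one, and with fry. An exact two-sided permutation of the sample labels was also run on each sample's median log2 value over the list. Its statistic was the difference between the group means of that median. The median is set by the members of middle brightness, so in a short list the changes of the others may not enter. With 4 against 4 samples the smallest p that permutation can give is 0.0286. It treats the 8 samples as exchangeable, and with 1 independent unit per group and set, 2 against 2, no p under 0.333 could be reached.

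The genes named were chosen by a rule written before the data were examined. They are PETC, the 10 largest rises and 10 largest falls among single-gene probes past the threshold with all 4 petc values on the same side of all 4 WT values, and up to 4 members with the smallest p of each fixed list with at least 3 measured members. Other genes are named as single measured members of a fixed list or as chosen after their values were seen.

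The replicate numbers were treated as pairing the samples in an alternative fit and not in the main one. All 4 pairs of samples with the same number deviated together from their group means, with Pearson r of 0.542 to 0.623 across probes, and each of the 8 samples correlated best with its own number. Between numbers 1 and 2, or 3 and 4, of different groups r was 0.369 to 0.442, so part of the likeness is not particular to the number. The pairing comes from the data, since no label says what a number marks. The limma fit without the block is the main one, and a fit with the number as a block was run as an alternative. Numbers 1 and 2 also stood apart from numbers 3 and 4 in both groups, and these are called the sets. This grouping was seen in the data and is not a label of the study. The 2 samples of a group and set are called duplicates for short, while a pair is a WT and a petc sample with the same number.

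Alternatives fixed before the data were examined were median centring, values as deposited, centring on the middle 50% of probes by brightness, leaving out the dimmest 25% or 50% of probes, zeros at the lowest positive value, an offset at the 5th percentile of positive values, an intensity trend with robust eBayes, a plain test per probe without moderation, the replicate block, and leaving out each sample. For lists, the estimated correlation, the mean over the probes of a gene and the mean fold change of a list were added to these. For the fit with an intensity trend and that with correlated readings, the lists were tested with cameraPR on the statistics of the fit. Chosen after the data were seen were the set as a block, the samples of a group and set as correlated readings (duplicateCorrelation), their means with and without the set as a block, each set alone, and counting probes whose several genes all lie in 1 list. A set alone holds 2 samples per group, so its p-values measure only the spread between duplicates.

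The fit was tested on simulated data for petc against WT: 20 data sets of 2947 probes with the real mean levels, components of spread estimated from these samples, and 200 changed probes, 50 for each size and direction. The main fit recovered 26.8% of probes changed by 0.5 on the log2 scale and 85.8% of those changed by 1, and 2.64% of its calls were false. With the replicate block the recovered shares were 65.1% and 97.7%, and 15.3% of the calls were false. With the duplicates as correlated readings they were 0.4% and 47.3%, and 0.105% of the calls were false. A share of false calls depends on how many probes changed and by how much, so these shares need not hold for the real data.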

Results

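Gene expression was compared between the Arabidopsis petc mutant and WT plants of the ecotype Landsberg, with 4 arrays per group. The mutant lacks the Rieske protein, the iron-sulfur subunit through which the cytochrome b6f complex passes electrons from plastoquinol towards photosystem I. The comparison asks which transcripts differ in abundance when this protein is missing. In each sample 2978 to 3009 of the 3439 probes were above 0. The median log2 intensity of these probes lay between -1.38 and -1.25, and the 10 brightest probes took 19.5% to 23.3% of the summed intensity. PETC itself was not analysed here, so the sample labels were not checked through the mutated gene.

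Transcripts changed in both directions in petc. Among genes with a named probe, AT4G39690, which encodes the MIC60 subunit of the mitochondrial inner membrane organising complex, rose 4.85-fold, and PRK, which encodes the Calvin cycle enzyme phosphoribulokinase, fell by a log2 fold change of -1.47 ± 0.13 (SE, n = 4 per group). In limma, 823 of 2947 probes passed the adjusted threshold, 373 higher and 450 lower in petc (448 higher and 385 lower with the values as deposited), and 223 of them changed by at least 2-fold, 110 up and 113 down. Of the 595 single-gene probes, 149 passed, 66 higher and 83 lower. The values of all 4 petc samples lay outside the range of the 4 WT samples for 794 of the 823 probes. Over all tested probes this held for 951 or 32.3%. Chance gives 2.86% for 8 independent samples and 33.3% if each group and set is 1 independent unit. Neither is a firm chance level here, since WT and petc shared the set difference (Pearson r = 0.696 across probes). With the replicate number as a block, 1374 probes passed, 654 higher and 720 lower, 816 of them among the 823. On simulated data 15.3% of the calls of that fit were false, against 2.64% in the main fit. Those data held 200 changed probes and gave fewer calls (192 and 116 on average), so the shares need not hold for the real counts. With the samples of a group and set as correlated readings, 345 passed, and with their means, 2 against 2, limma called 0 probes while 585 had an unadjusted p below 0.05.

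Among the single-gene probes eligible under the naming rule, the largest rises were in genes of several functions. Over all called probes the largest rise was 3.13 on the log2 scale, on a probe outside that rule. AT4G39690 went from 0.871 ± 0.165 in WT to 4.71 ± 0.593 in petc (deposited intensity, SD, n = 4), a log2 fold change of 2.28 ± 0.17 (SE) with limma adjusted p = 4.99e-05. AT5G52810, the reductase SARD4 of pipecolic acid synthesis, rose from 0.724 ± 0.156 to 3.77 ± 0.274, by 2.24 ± 0.16 on the log2 scale (limma adjusted p = 5.09e-05). AT3G06570, a gene of the kelch repeat F-box family, rose by 1.84 ± 0.12 (limma adjusted p = 4.44e-05). AT5G44000, a glutathione S-transferase family gene, rose by 1.79 ± 0.17 (limma adjusted p = 0.000184). AT3G26630, a pentatricopeptide repeat gene, rose by 1.57 ± 0.12, AT4G09620, a gene of the mTERF family, by 1.44 ± 0.27, and AT2G37510, which encodes an RNA-binding protein, by 1.41 ± 0.12. AT4G31530, a gene of the Rossmann-fold NAD(P)-binding family, went from 33.1 ± 7.96 to 76.0 ± 11.4, a log2 fold change of 1.35 ± 0.20 that was 0.81 in numbers 1 and 2 and 1.89 in numbers 3 and 4. AT2G22890 rose by 1.31 ± 0.09.

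AT3G07790 also passed, with a log2 fold change of 1.401 ± 0.413 and limma adjusted p = 0.0372, but its change was 0.64 in numbers 1 and 2 and 2.17 in numbers 3 and 4. Its call was lost without WT replicate 3 (limma adjusted p = 0.0853), WT replicate 4 (0.0799), petc replicate 1 (0.0799), petc replicate 2 (0.0763), petc replicate 3 (0.0783) or petc replicate 4 (0.0740), and its adjusted p ranged from 0.00383 to 0.297 over all alternatives.

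The 10 largest falls included PRK and genes of several families. AT2G06040 had the largest fall, a log2 fold change of -3.81 ± 0.50 (SE, limma adjusted p = 0.00093), at a dim deposited intensity of 0.0570 ± 0.0141 in WT and 0.00697 ± 0.00224 in petc (SD, n = 4); with the values as deposited the change was -3.07, and with an offset before log2 it was -0.83, smaller than the -2.06 of AT2G36480 with that offset. AT2G36480 went from 4.29 ± 0.533 to 1.13 ± 0.0759, a change of -2.13 ± 0.12 (limma adjusted p = 2.62e-05). AT5G49840, a gene of the ClpX chaperone family, changed by -2.001 ± 0.430 (limma adjusted p = 0.00986), with -2.62 in numbers 1 and 2 and -1.38 in numbers 3 and 4. AT4G03150 changed by -1.77 ± 0.12, AT4G34310, an alpha/beta-hydrolase family gene, by -1.56 ± 0.11, and AT1G01500 by -1.47 ± 0.16. PRK went from 1.79 ± 0.0978 to 0.696 ± 0.0887 (limma adjusted p = 0.000135). AT5G05400, a gene of the NB-ARC and leucine-rich repeat family of resistance proteins, changed by -1.29 ± 0.23 (limma adjusted p = 0.00477).

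AT3G56010 changed by -1.52 ± 0.27 (limma adjusted p = 0.00471), and by -0.78 with an offset before log2. With the samples of a group and set as correlated readings its adjusted p was 0.126, and in numbers 1 and 2 alone 0.0704, in a range of 0.00136 to 0.126 over all alternatives. AT3G50350 changed by -1.44 ± 0.41 (limma adjusted p = 0.0325). Its call was lost without WT replicate 3 (limma adjusted p = 0.0807), WT replicate 4 (0.0822), petc replicate 1 (0.0795) or petc replicate 2 (0.0723), and the range over all alternatives was 4.16e-05 to 0.273.

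**Figure D1:**
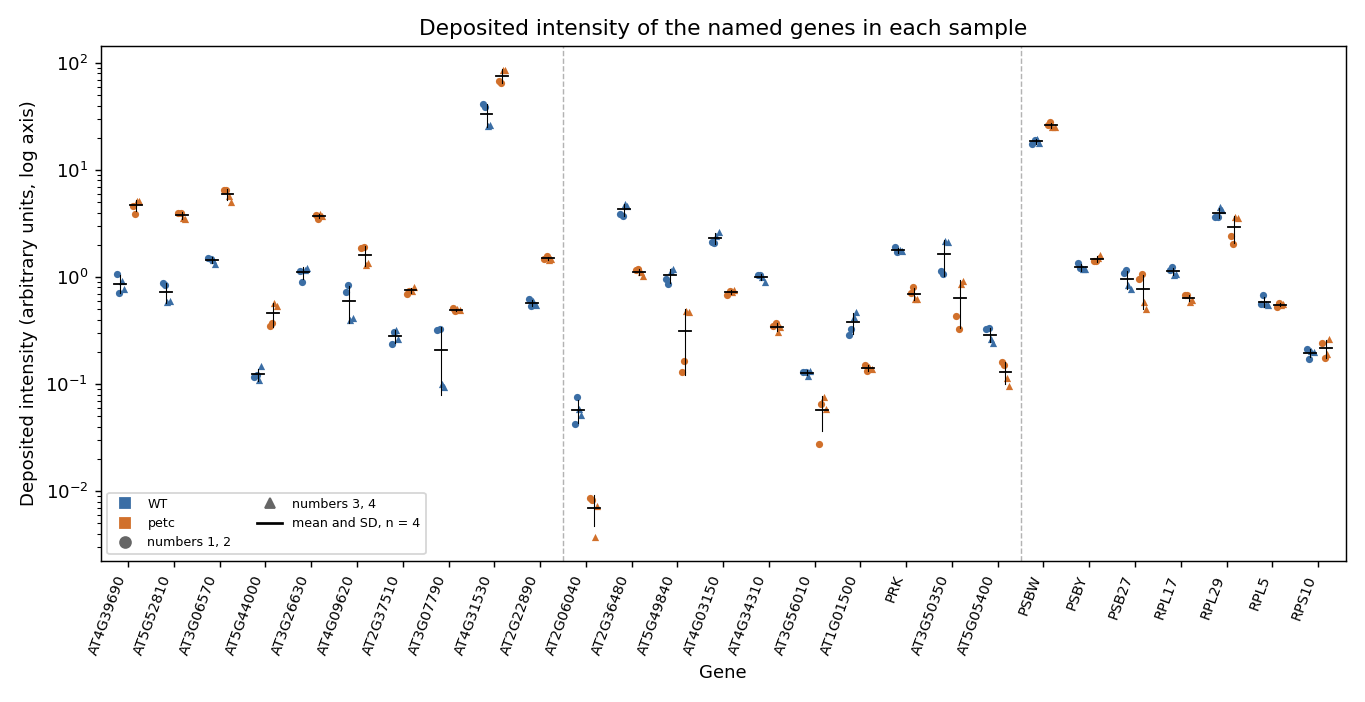
Deposited intensity (arbitrary units, log axis) of the genes named by rule in each of the 8 samples. WT is blue and petc orange, circles are numbers 1 and 2 and triangles numbers 3 and 4, and black lines give the mean and SD (n = 4). The left block holds the largest rises, such as AT4G39690 from 0.871 to 4.71, the middle block the largest falls, such as PRK from 1.79 to 0.696, and the right block the list members.

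Of the photosystem II subunits, 3 genes were measured and 1 rose. PSBW, a small subunit of the photosystem II core, went from 18.5 ± 0.882 to 26.3 ± 1.43 (deposited intensity, SD, n = 4), a log2 fold change of 0.45 ± 0.10 (SE, limma adjusted p = 0.00955). Its call was lost with the samples of a group and set as correlated readings (adjusted p = 0.101), with their means with the set as a block (0.0545) and in numbers 3 and 4 alone (0.0506), in a range of 0.00175 to 0.283 over all alternatives. PSBY had a log2 fold change of 0.16 ± 0.10 (limma adjusted p = 0.269), with 0.30 in numbers 3 and 4 alone, where it passed (0.0459), and 0.03 in numbers 1 and 2 alone (0.880), in a range of 0.0459 to 0.880 over all alternatives. PSB27, an assembly factor, had -0.37 ± 0.29 (limma adjusted p = 0.395), and 0.0413 with the replicate number as a block, a call lost with the duplicate means and the set as a block (0.136), in a range of 0.0285 to 0.715 over all alternatives. It had -0.15 in numbers 1 and 2 alone (limma adjusted p = 0.281) and -0.59 in numbers 3 and 4 alone, where it passed (0.0289). For all 3 genes, a fit of 1 set alone measures only the spread between duplicates. Adjusted over the list alone, 1 gene passed as well. The list did not pass in camera, which compares it with the other genes (adjusted p = 0.317, and adjusted p = 0.414 with an estimated correlation). With 3 genes this leaves open whether the list shifted. The exact permutation p of its per-sample median was 0.0857, but PSBY was the middle gene in every sample, so this tested PSBY alone. The fry test of limma, for a shift on balance one way and without comparison with other genes, gave adjusted p = 0.0331, upward. It took all 8 samples as independent.

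Of the plastid ribosomal proteins, 4 genes were measured and 2 fell. RPL17 went from 1.13 ± 0.0947 to 0.639 ± 0.0459 (deposited intensity, SD, n = 4), a log2 fold change of -0.85 ± 0.12 (SE, limma adjusted p = 0.00124). RPL29 went from 4.01 ± 0.448 to 2.91 ± 0.807, a change of -0.82 ± 0.17 (limma adjusted p = 0.00885). The RPL29 call depended on quantile normalisation, as the change was -0.53 with limma adjusted p = 0.0656 after median centring, 0.0653 after centring on the middle 50% of probes, and -0.50 with adjusted p = 0.110 as deposited, in a range of 0.000339 to 0.200 over all alternatives. RPL5 (-0.09 ± 0.10) and RPS10 (0.06 ± 0.15) did not pass. Adjusted over the list alone, 2 genes passed. The list did not pass in camera (adjusted p = 0.187, and adjusted p = 0.279 with an estimated correlation). The fry test, which does not compare the list with other genes, gave adjusted p = 0.000136, downward. The exact permutation of the list's per-sample median gave p = 0.0286, the smallest it can give. In every sample that median was the mean of RPL17 and RPL5, so it took nothing from the changes of RPL29 and RPS10.

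Of the other fixed lists, 6 had 1 or 2 measured members and 12 had 0, and PRK was the measured gene of the Calvin cycle list. FATB, the acyl-ACP thioesterase that releases saturated fatty acids in the plastid, fell by a log2 fold change of -0.98 ± 0.16 (SE, limma adjusted p = 0.0029), or -0.65 with an offset before log2, and its adjusted p was 0.084 with the samples of a group and set as correlated readings, in a range of 0.0011 to 0.104. LHCB1.5, a light-harvesting protein of photosystem II, had -0.32 ± 0.12 (limma adjusted p = 0.0854); it passed as deposited (0.0249) and after median centring (0.0298), in a range of 0.0249 to 0.436. PSAN, a photosystem I subunit, had -0.02 ± 0.09 (limma adjusted p = 0.873), but 0.28 with adjusted p = 0.0358 as deposited and 0.25 after median centring, so its direction turned with the scaling (adjusted p from 0.0358 to 0.957 over all alternatives). CHLP, which reduces geranylgeranyl chains for chlorophyll, had 0.08 ± 0.09 (limma adjusted p = 0.614), and 0.26 with adjusted p = 0.049 as deposited, in a range of 0.049 to 0.881. CHLM, a chlorophyll synthesis methyltransferase, had 0.22 ± 0.15, and NTRC, a plastid thioredoxin reductase, 0.13 ± 0.12, and neither passed. PRXIIE, a plastid peroxiredoxin, had -0.54 ± 0.30 (limma adjusted p = 0.237), and 0.0235 with the replicate number as a block. It passed in numbers 3 and 4 alone (-0.71, 0.0119) but not in numbers 1 and 2 alone (-0.37, 0.246), in a range of 0.0106 to 0.568. The fits of a set alone measure only the spread between duplicates. Over all 15 measured genes of the fixed lists, 5 passed, 1 higher and 4 lower, and 7 with the block, 1 higher and 6 lower. With the 15 genes adjusted together 5 passed, and adjusted over the list alone, each list by itself, 6 passed, with LHCB1.5 added, the single measured gene of its list, whose p is then unadjusted. With the duplicate means and the set as a block 5 passed, 0 higher and 5 lower, without PSBW and PSB27, and as deposited 7 passed, 3 higher and 4 lower.

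The samples of a group fell into sets by replicate number. Within a group and set, Spearman's rho across probes was 0.975 to 0.988, and between the sets of a group 0.902 to 0.923, close to the 0.898 to 0.922 between petc and WT of the same set. PC1 took 45.3% of the variance and separated petc from WT, and PC2 took 33.8% and separated the sets. The median SD of a probe was 0.239 in WT and 0.206 in petc on the log2 scale (n = 4), but 0.127 and 0.108 within sets. Fold changes computed in the sets separately correlated across probes with Pearson r = 0.761 and Spearman rho = 0.763, where probes are not independent replicates. Of all tested probes 79.2% had the same direction in both sets, and all 823 past the threshold did, a selection that itself favours such probes. Numbers 1 and 2 alone gave 684 probes past the threshold and numbers 3 and 4 alone 1036. Each of these fits compared 2 duplicates with 2, so its p-values measure only the spread within a set.

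**Figure D2:**
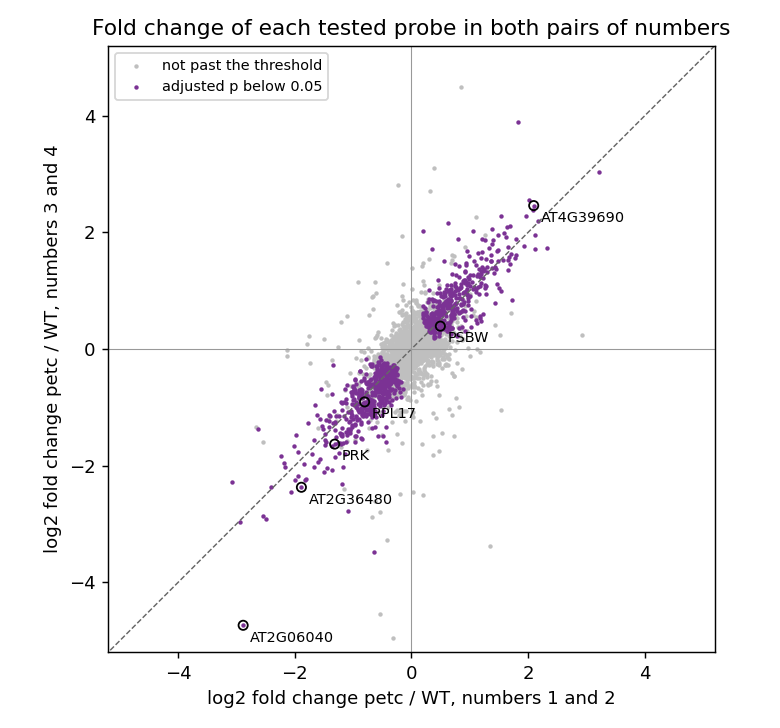
Log2 fold change of petc over WT for each tested probe from numbers 1 and 2 (x axis) and from numbers 3 and 4 (y axis). Purple points passed the threshold over all 8 samples, circles mark named genes, and the dashed line marks equal values. The purple points lie in the upper right and lower left quadrants, and across all probes r = 0.761.

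**Figure D3:**
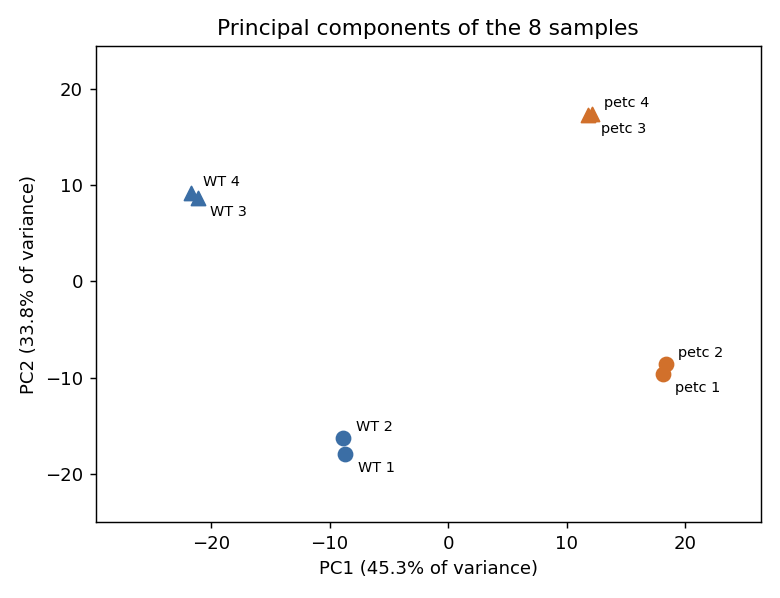
Position of the 8 samples on PC1 (45.3% of variance) and PC2 (33.8% of variance) of the normalised log2 values. WT is blue, petc orange, circles are numbers 1 and 2 and triangles numbers 3 and 4. The groups separate along PC1 and the sets along PC2, and the samples of a group and set lie beside each other.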

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

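Which measurements stood apart within their group was tested for 76 groups of 4 samples, covering the named genes, the list members and the sample totals. In all 5 stood out, where chance gives about 3.8 for independent samples. The 4 samples of a group form 2 sets of close duplicates, so 3.8 is not a firm chance level. Of the 5 that stood out, 3 were gene values. The AT3G26630 log2 value of WT replicate 2 was -0.18 against a median of 0.25 in the other WT samples, a small part of the gene's rise of 1.57. The AT4G34310 log2 value of WT replicate 4 was -0.15 against 0.04 in the others. The RPS10 log2 value of WT replicate 2 was -2.53 against -2.23 in the others.

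The number of probes listed at 0 was 440 in WT replicate 1, where the other WT samples had a median of 431, and 461 in petc replicate 4, where the other petc samples had a median of 455.

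Among probes at 0 in all 4 WT samples, and so outside the tests, 2 gave a signal in all 4 petc samples. Probe 1802 had a mean deposited intensity of 0.392 in petc, with 0.305 to 0.443 in the single samples. Probe 4174 had a mean of 0.0425, with 0.00138 to 0.0938. Neither has a gene name in the annotation, and no fold change is given because the WT values are listed at 0.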

How the results depend on the processing

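The replicate block and all other alternatives named as fixed before the data were examined were planned, and the sets, the correlated readings and the duplicate means were chosen after seeing the data. The count of 823 probes, 373 higher and 450 lower, stayed within a factor of 1.5 under every scaling, filter, offset and variance model tried, but with the values as deposited 448 were higher and 385 lower, so the balance of rises and falls turned. It moved with the treatment of the replicates. With the replicate block it was 1374 (654 higher, 720 lower) and with the set as a block 1358 (634 higher, 724 lower). With the duplicates as correlated readings it was 345 (163 higher, 182 lower), and list members past the threshold numbered 3. With duplicate means limma called 0 probes (0 higher, 0 lower, 585 at an unadjusted p below 0.05) and 0 list members, while with the set as a block the duplicate means gave 796. The block removes the set difference from the residual spread, which the duplicate means keep. The replicate block still counts the duplicates as separate pairs. On simulated data with 200 changed probes 15.3% of its calls were false, against 2.64% in the main fit. These shares need not hold for the real counts. Without each sample in turn the count was 627 to 725, with 282 to 344 higher and 337 to 391 lower, and list members stayed at 5. The median SD of WT was 0.0964 in numbers 1 and 2 alone and 0.101 in numbers 3 and 4 alone, and that of petc 0.0936 and 0.0769.

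Neither tested list passed in camera or cameraPR in the settings run for lists, where the adjusted p of the photosystem II subunits was 0.195 to 0.598 and that of the plastid ribosomal proteins 0.0949 to 0.279. The plain test per probe was not run for lists, and the mean of a list and the mean over probes are values with no test. Fry is given for the main setting only. That setting takes the 8 samples as independent, while the duplicates had a consensus correlation of 0.674 in duplicateCorrelation. The replicate block turned 2 named genes, PSB27 and PRXIIE, into calls and changed no other call of the 34 named genes. With duplicate means all 24 called named genes lost the call, and with the duplicates as correlated readings 5 did. The plain test and zeros at the lowest positive value each ended 2 calls, AT3G07790 and AT3G50350, and the cause was not tested. None of the 24 named genes called in the main setting changed direction under an alternative, but PSAN was above 0 and called as deposited and below 0 and not called in the main setting. PETC was not analysed here, so none of its alternatives was run. Of the brightest 25% of probes 46.9% were called, and of the dimmest 25% 118 of 737, so dim probes limit what can be called.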

Other observations

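The gene lists and the tests in this part were chosen after the largest changes had been seen. Of 22 measured genes of the pentatricopeptide repeat and mTERF families, 2 rose, AT3G26630 and AT4G09620, and 3 fell in limma: AT2G19280 by -1.27 ± 0.10 (log2 fold change, SE, adjusted p = 7.32e-05), AT1G61990 by -0.69 ± 0.12 (adjusted p = 0.00323) and AT1G62010 by -0.63 ± 0.09 (adjusted p = 0.00179). With the replicate number as a block, 3 were higher and 7 lower, and of the calls this added, the rise of AT4G04370 (adjusted p = 0.0391) was lost with the duplicate means and the set as a block (0.202). Without the block the other 17 did not pass, and of all 595 single-gene probes 149 did. The list as a whole did not pass in camera (adjusted p = 0.432, and adjusted p = 0.426 with an estimated correlation), while fry, which does not compare it with other genes, gave adjusted p = 0.00329, downward, over the 4 lists of this part. In these families close relatives can share signal on an array.

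Of 6 measured plastid redox enzymes, 2 fell in limma. FTRB, the catalytic subunit of ferredoxin-thioredoxin reductase, which passes electrons from ferredoxin to thioredoxins, had -0.78 ± 0.18 (log2 fold change, SE, adjusted p = 0.0137), and CCS, the copper chaperone of superoxide dismutase, had -0.47 ± 0.10 (adjusted p = 0.011). Both calls were lost with the duplicates as correlated readings (adjusted p = 0.119 and 0.152), and that of CCS also with the duplicate means and the set as a block (0.0544). With the replicate block 4 were lower, with NADP-MDH (adjusted p = 0.00908) and PRXIIE (0.0235) added, but with the duplicate means and the set as a block NADP-MDH did not pass (0.0933) and PRXIIE did (0.0468). Camera did not pass for this list (adjusted p = 0.432), and fry gave adjusted p = 0.00329, downward. The exact permutation p of its per-sample median was 0.0286, the smallest it can give, but that median is set by the members of middle brightness. Among 8 measured genes for assembly and upkeep of thylakoid complexes, only NdhS of the chloroplast NADH dehydrogenase-like complex passed without the block, at 0.41 ± 0.08 (adjusted p = 0.00642), and it lost the call with the duplicates as correlated readings (0.0754) and with the duplicate means and the set as a block (0.0686). With the block LPA19 was also higher (adjusted p = 0.0345) and PSB27 lower, and neither passed with the duplicate means and the set as a block (0.122 and 0.136). CCB3, a factor for attaching a heme to cytochrome b6, had 0.05 ± 0.15 and did not pass. Of 7 histone H3 and kinesin genes, AT1G13370 had -1.23 ± 0.37 (adjusted p = 0.0413) and AT2G37420 -0.60 ± 0.17 (adjusted p = 0.0347), and both calls were lost with the duplicates as correlated readings (0.102 and 0.370). With the block 4 were lower, of which AT5G65360 (adjusted p = 0.0458) and AT1G09200 (0.0152) did not pass with the duplicate means and the set as a block (0.186 and 0.0613). Histone H3 genes are near-identical copies, so these values are uncertain. For the thylakoid list camera gave adjusted p = 0.516 and fry adjusted p = 0.0379, upward, with a median log2 fold change of -0.01 and a mean of 0.01. For the histone and kinesin list camera gave adjusted p = 0.432 and fry adjusted p = 0.0379, downward.

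Probes annotated to several genes that all lie in 1 fixed list numbered 7, and 2 of them passed, both lower in petc: an antioxidant probe by -1.29 ± 0.17 (limma adjusted p = 0.0011) and a starch and sugar probe by -0.52 ± 0.12 (adjusted p = 0.015). There were also 3 probes above 0 in all 4 WT samples and at 0 in all 4 petc samples.

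The count of probes past the threshold between petc and WT was set against other splits of the 8 samples. Only 1 of the 35 splits, the real one, gave as many as 823, which argues against a chance split only if the 8 samples are exchangeable. The highest other, 531, was the split of numbers 1 and 2 from numbers 3 and 4, and apart from it no split gave more than 1. With the set as a block the real comparison gave 1358. Of the 8 splits that part all 4 pairs, the 7 besides the real one gave 0 probes, with and without the block, but 8 splits are too few for a share under 0.05. With the duplicates as correlated readings, 345 probes or 11.7% of those tested passed. That fit still estimates the spread from all 8 readings. It therefore cannot exclude that the count arose from duplicates counted as separate replicates. If the duplicates of a group and set came from 1 plant sample, only 2 independent samples per group remain, and duplicate means without the set as a block gave 0 calls, so how far the changes extend to other plants stays open.

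The difference between numbers 1 and 2 and numbers 3 and 4 was alike in WT and petc. A brightness-dependent scaling or response is argued against, since the set differences of both groups still correlated at r = 0.709 across probes after quantile normalisation and removal of the trend with brightness. The set difference of neighbouring probe numbers correlated at r = 0.497, where the highest of 1000 shuffled orders gave 0.0511, and r was 0.204 for probes 8 places apart and 0.00078 for probes 24 places apart, while the petc to WT fold change of neighbours had r = -0.04. A candidate explanation for part of the difference is therefore the making or reading of the arrays in the order of the probes. Whether it is the whole cannot be told. The groups' differences correlated at r = 0.696, and at 0.567 after the mean of the 10 nearest probes was subtracted. That mean predicted only 33.4% of the variance of the set difference, so finer effects of position could remain. Neighbours and places were counted among the 2947 tested probes in the order of their numbers. These numbers run to 4607, so neighbours need not have adjacent numbers. The sources used here do not say that probe numbers give positions on the array. The design names no biological difference between the sets, so no biological explanation was tested.

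The scaling of the deposited values bears most on bright and dim probes. In the brightest 10% of probes the median deposited log2 fold change of petc over WT was 0.10 and after quantile normalisation -0.04, and in the dimmest 10% it was 0.15 and -0.09. PSAN and CHLP, with calls only as deposited, and RPL29, with a call lost there, lie at brightness percentiles of 97.5, 94.5 and 97.0 among single-gene probes. LHCB1.5 and PSBW were brighter still, at 99.7 and 99.5. As deposited LHCB1.5 was lower, with -0.38 against -0.32 in the main setting, and PSBW had 0.50 against 0.45. Bright genes therefore did not all move alike with the scaling.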
